A study of Mus musculus with 4 samples.

How the data were processed

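Single-nucleus RNA of mouse left and right cervical vagus nerves, containing the nodose ganglion, was available as 4 libraries: 2 of P-PTEN KO and 2 of P-PTEN WT mice, all after 2 weeks of a diet with 60% fat begun after 6 weeks of age. Per the design text, 14 nerves of 7 animals were pooled into 1 sample for each cohort. How 2 libraries of each genotype came from that is not stated, so they were taken as the replicate unit with the limit that they may be repeats of 1 pool. Per the labels' protocols, tissue was flash frozen and dounced, nuclei were sorted with trypan blue, and libraries were made with the 10x 3' kit, version 3. Counts are the deposited matrices of UMI counts per gene and barcode, which the authors made with Cell Ranger. The labels' protocols give its version as 3 and the matrix headers, per the file headers, as 7.0.0. The submitters' processing notes name both GRCh38 and mm10; the gene identifiers of the matrices are mouse and number 32285 in each library. Raw reads were not used here, and the chow-fed animals and the tissues of the wider study were not analysed here. Per the design text the authors clustered with Seurat and Harmony in RStudio 4.2.2.

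Lowest barcodes held 500, 500, 507 and 500 UMIs (KO1, KO2, WT1 and WT2), so barcodes of lower counts were not in the deposited matrices and free RNA could not be estimated from them. Whether some of the deposited barcodes are empty droplets was not tested. Genes with a count numbered 21014, 23041, 22502 and 21487, and 40 matrix entries repeat a gene symbol and were kept apart by identifier. Barcodes with fewer than 200 genes (0, 264, 0 and 443) or over 5% mitochondrial counts (384, 118, 39 and 66) were removed. Doublets were called within each library with Scrublet in scanpy, with exact neighbours and an expected share of doublets that grew with the number of nuclei, and 6, 139, 1 and 3 barcodes were removed. The 8191 nuclei kept held 3502862, 9613739, 5929321 and 6024006 UMIs.

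Clustering used python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9; figures used matplotlib 3.10.9. Log-normalised counts of 2000 variable genes chosen within libraries gave 30 principal components. These were corrected for library by the Harmony algorithm, coded here since the package was not installed (theta 2, sigma 0.1, lambda 1, 10 rounds). A graph of 15 exact nearest neighbours was clustered with Leiden at resolution 0.6 and seed 1. Clusters were named from 25 fixed marker lists. The score was the mean positive log2 fold of a list's genes over the other clusters with 20 CPM added, with at least 3 genes detected in 10% of nuclei at a log2 fold of 1 or more, and clusters where a second list scored over 0.5 of the first stayed unnamed. The first form of this rule left the neuron cluster unnamed because sympathetic markers rivalled the neuron list, and after that was seen it was changed so that sympathetic markers count towards the neuron class. Clusters of the same name were joined, and classes with at least 10 nuclei in each of the 4 libraries were tested; B cell and T or NK cell nuclei fell short of that.

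Before the data were examined, the comparisons, tests, 26 gene lists, marker lists, alternatives and the rule for naming genes were written down. Counts were summed per library and class in R 4.3.3. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM factors, robust quasi-likelihood fit, two-sided F test, no covariates), adjusted by Benjamini-Hochberg over the genes of a class at a threshold of 0.05. DESeq2 1.42.0 was run beside it. Fold changes are KO over WT on the log2 scale, and within-number values compare KO1 with WT1 and KO2 with WT2. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a class. Camera asks whether a list's genes rank apart from all others, and its preset correlation is small for genes of 1 pathway, so each call is given beside the p with an estimated correlation. That form takes its degrees of freedom from the 4 libraries in 2 groups, so few that it has very little power. A call lost there is therefore not shown to be false. Nuclei per class were compared by edgeR on the table of nuclei counts, with exact Clopper-Pearson intervals and an exact permutation test over libraries. The difference of the KO effect between neuron-class nuclei and each other class was tested with edgeR's genotype by class term, with library as a block.

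Genes were named by the fixed rule: in each class, those with adjusted p under 0.05, mean log2 CPM of at least 5, both KO libraries on the same side of both WT libraries and no gene-model symbol. Over all nuclei and in the main classes (neuron, myelinating Schwann, non-myelinating Schwann and perineurial) these were the 12 largest rises and 12 largest falls, and in each other class up to 6 genes, the 3 largest of each direction. Where fewer than 5 passed in a direction, genes of smallest p were added as not passing, up to 5 in the main classes and up to 3 in the others. Pten, list members that passed and up to 4 list members of highest level were named too. Genes outside the rule are said to be so where they stand. A fold against a group with 0 UMIs is given as at least the ratio to 3 UMIs over the group, and with 1 to 3 UMIs as a ratio with an exact counting interval.

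The lists were: PI3K-AKT-mTOR pathway, insulin and IGF signalling, FoxO targets, cholesterol and fatty acid synthesis, lipid storage and fatty acid oxidation, axon regeneration and nerve injury, vagal sensory receptors, nodose neuron identity, jugular neuron identity, transmitters and neuropeptides, voltage-gated channels, myelin, repair Schwann cell, inflammatory mediators, antigen presentation and interferon response, extracellular matrix, autophagy and lysosome, nuclear-encoded respiratory chain, unfolded protein response, immediate early, circadian clock, cytosolic ribosomal proteins, mitochondrially encoded, haemoglobin, heat shock and sex-linked genes.

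Alternatives fixed in advance were RLE size factors, library sizes alone, DESeq2, no count filter, a stricter one (a mean of 10 counts and 5 in every library of 1 genotype), each library left out, the replicate number as a block, sums thinned to the smallest library, doublets kept, nuclei with at least 500 genes and at most 1% mitochondrial counts, components with no library correction, resolutions 0.3 and 1.2, an estimated correlation, fry and a prior count of 0.5. Leaving out the forebrain nuclei of KO2 and clustering without the genes called in muscle were added after the data were seen. Nuclei with at least 3 of the forebrain genes counted as forebrain nuclei.

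The gene and list tests were run on counts simulated for each class from a profile pooled over its libraries. Library depths were those of the data, and the spread was that fitted to genes of like level. For the erythroid class this left 801 genes tested against 2719 in the data, so its recovery does not give the power there. Of 100 genes given a 4-fold change, edgeR recovered 13 over all nuclei, 67 in adipocytes, 31 in endothelial, 0 in erythroid, 61 in fibroblast, 59 in macrophage, 53 in myelinating Schwann, 50 in non-myelinating Schwann, 0 in neuron, 23 in pericyte or smooth muscle, 71 in perineurial and 4 in muscle nuclei. Of 100 genes given a 2-fold change, edgeR recovered at most 13 in any class (fibroblast) and 0 over all nuclei. Of simulated lists with a 2-fold change 20 of 24 were found. Among the 360 others, 0 lists that share no member with the changed list were called, and calls of those sharing members were left out. Genes were simulated independently, so false calls of lists whose genes vary together were not tested. All 14 simulated 4-fold changes in nuclei per class were found, with 48 of 182 others called. Those shares varied by counting error alone, so this does not give the power at the spread between these libraries. Clustering with the library correction placed 100% of 1600 simulated nuclei with their own kind, against 95.0% without it. These were drawn at a fixed depth from 5 classes named by the same markers, so naming in the real data was not tested.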

Results

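Single-nucleus RNA sequencing was applied to the left and right cervical vagus nerve of mice, dissected together with the nodose ganglion, which holds the cell bodies of vagal sensory neurons. Mice labelled P-PTEN KO were compared with mice labelled P-PTEN WT, both after 2 weeks on a high-fat diet, and the labels do not say what the letter P stands for. Each genotype had 2 libraries, named KO1, KO2, WT1 and WT2 here, and values given as a series of 4 follow that order. The design text describes 14 nerves of 7 animals pooled into 1 sample for each cohort and does not say how 2 libraries came from it. The spread between the libraries of a genotype can therefore be that of technical repeats, and every p-value below carries that limit.

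The deposited matrices held 1229, 4680, 806 and 2939 barcodes with 4008899, 10978874, 6035236 and 7478262 UMIs (counted mRNA molecules). After filtering, 839, 4159, 766 and 2427 nuclei remained, 8191 in all, with a median of 2795, 1566, 5419 and 1730 UMIs per nucleus. Haemoglobin transcripts took 0.118%, 9.56%, 0.00804% and 21.9% of the UMIs, so KO2 and WT2 stood apart from KO1 and WT1 in red-cell RNA. Mitochondrial transcripts took 1.82%, 0.769%, 0.453% and 0.652%, and 31.2% of the KO1 barcodes exceeded the limit of 5% against 2.52%, 4.84% and 2.25% of the others.

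Clustering gave 21 clusters, of which 20 could be named from marker genes as cells of a known kind, in the sense of being like them; the suffix is left out below. Myelinating Schwann nuclei, which wrap large axons and express Mpz, Prx and Mbp, numbered 126, 1036, 100 and 380. Non-myelinating Schwann nuclei, marked by Scn7a and L1cam, numbered 122, 602, 112 and 283, and perineurial nuclei of the nerve sheath, marked by Slc2a1 and Cldn1, numbered 47, 551, 105 and 520. Adipocyte nuclei numbered 177, 379, 73 and 468, and fibroblast nuclei 50, 687, 74 and 242. Smaller classes were endothelial (147, 97, 40 and 219), macrophage (30, 224, 25 and 53), skeletal muscle (27, 284, 16 and 13), erythroid (53, 86, 49 and 69), neuron (14, 67, 104 and 22), pericyte or smooth muscle (26, 12, 16 and 17), B cell (7, 32, 12 and 81) and T or NK cell (10, 55, 6 and 37). Of the erythroid class, only 9.43% of KO1 and 20.4% of WT1 nuclei had 2 or more of its markers, against 100% in KO2 and WT2. That class therefore held unlike nuclei in different libraries. Cluster 17, with 107 nuclei, carried markers of both non-myelinating Schwann cells and satellite glia and stayed unnamed.

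Pten, the targeted gene, encodes the lipid phosphatase that opposes PI3K signalling. It lies on the plus strand of chromosome 19 at 32757497 to 32826160 (mm10; protein coding; 9 exons in transcript Pten-201, the last of them at 32819843 to 32826160), and the matrices list it as ENSMUSG00000013663. Its level over all nuclei was 385, 400, 311 and 333 CPM (its UMIs over all UMIs of the nuclei, times 1e6), or 393 ± 10.7 in KO and 322 ± 15.4 in WT (mean ± SD, n = 2). The log2 fold change, KO over WT, was 0.27 with a standard error of 0.28 (edgeR quasi-likelihood test, two-sided, adjusted p = 0.9999). In myelinating Schwann nuclei Pten was at 353 and 364 CPM in KO against 294 and 295 in WT (log2 fold change 0.29, SE 0.20, edgeR adjusted p = 0.9999). Non-myelinating Schwann nuclei had 668 and 733 CPM against 523 and 614 (0.29, SE 0.20, edgeR adjusted p = 0.9995), and perineurial nuclei 228 and 233 against 175 and 184 (0.38, SE 0.20, edgeR adjusted p = 0.9996). Nuclei of the neuron class had 562 and 179 CPM against 188 and 191, from 11, 164, 228 and 21 UMIs (log2 fold change 0.53, SE 1.03, edgeR adjusted p = 0.9997). The KO nuclei of that class were mixed: only 3 of 14 in KO1 had 2 or more neuron markers, and in KO2 487152 UMIs came from 19 nuclei with forebrain genes and 427865 from the other 48. The log2 fold change of Pten in the neuron class was 0.18 without KO1. The other classes gave log2 fold changes of -0.05 in adipocytes, -0.32 in muscle, 0.16 in fibroblasts, 0.36 in macrophages, 0.56 in endothelial, 0.74 in pericyte or smooth muscle and 0.84 in erythroid nuclei, none of which passed. In muscle the means ran the other way, 181 CPM in KO and 171 in WT, with 2 UMIs in WT2 (within numbers -0.06 and 0.28). In the erythroid class, which held unlike nuclei in different libraries, Pten stood at 503, 19.0, 224 and 7.34 CPM. A 95% interval of the KO over WT ratio was taken with 2 degrees of freedom, fewer than the edgeR test used, so it is wider than that test implies. It reached down to 0.529 over all nuclei, 0.667 in myelinating Schwann, 0.672 in non-myelinating Schwann, 0.707 in perineurial and 0.0666 in neuron nuclei. No fall in Pten passed in any class tested, and the labels give neither the deleted exons nor the cells that carry the deletion. A 3' tag outside the deleted exons checks nothing, so these values do not test the genotype labels.

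**Figure D1:**
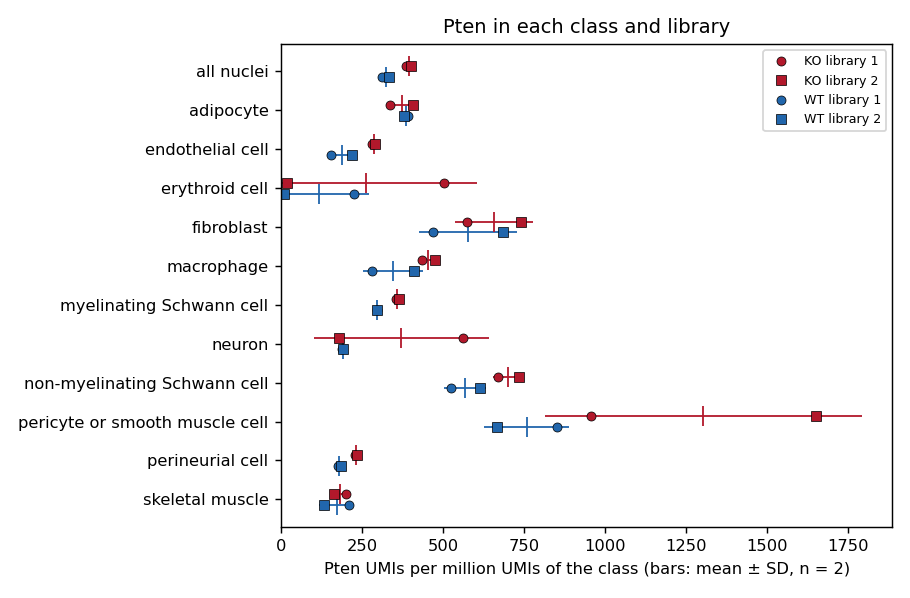
Pten level in CPM of the class (horizontal axis) for all nuclei and each class tested, with 1 point per library (red KO, blue WT) and bars for the mean ± SD of the 2 libraries. Over all nuclei the KO libraries lay at 385 and 400 and the WT libraries at 311 and 333.

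The first comparison concerned which kinds of nuclei the nerves of each genotype yielded. Perineurial nuclei made up 9.43% ± 5.41 of KO and 17.6% ± 5.46 of WT libraries (mean ± SD, n = 2), B cell nuclei 0.802% ± 0.0459 and 2.45% ± 1.25, and macrophage nuclei 4.48% ± 1.28 and 2.72% ± 0.764, with both KO libraries on the same side of both WT libraries. Skeletal muscle nuclei made up 5.02% ± 2.55 of KO and 1.31% ± 1.10 of WT libraries, with log2 ratios of 0.62 between KO1 and WT1 and 3.67 between KO2 and WT2. Trim63 and Fbxo32, which are among the leading genes of that cluster, differed between the genotypes. Clustering without the 34 genes called in muscle gave 27, 280, 15 and 13 muscle nuclei and a log2 ratio of 2.06 (edgeR adjusted p = 0.395), a setting chosen after the data were seen. Nuclei of the neuron class were 13.6% of WT1 (exact Clopper-Pearson 95% interval 11.2 to 16.2%) but 0.906% of WT2 (0.569 to 1.37%), against 1.67% and 1.61% of the KO libraries. Only 3 of its 14 KO1 nuclei had 2 or more neuron markers, and 19 of its 67 KO2 nuclei carried forebrain genes, so these shares are not shares of like neurons. Log2 ratios were 2.01 for muscle, -2.12 for the neuron class, -1.63 for B cells, -0.89 for perineurial, 0.73 for macrophage, 0.48 for myelinating Schwann and 0.46 for endothelial nuclei. Cluster 17 had -1.73, and the other classes lay between -0.15 (erythroid) and 0.25 (pericyte or smooth muscle). Erythroid shares were not shares of like nuclei either, since few KO1 and WT1 nuclei of that class had 2 or more of its markers. No class passed edgeR's two-sided test on nuclei counts (smallest edgeR adjusted p = 0.439, for muscle, neuron, B cell and cluster 17 nuclei), and none had an unadjusted p under 0.05. An exact two-sided permutation test over 4 libraries cannot go below 0.333. Without 1 library the log2 ratio ranged from 1.28 to 3.23 for muscle, -2.06 to -0.97 for B cell, -1.65 to -0.41 for perineurial, 0.40 to 1.04 for macrophage, 0.06 to 0.79 for myelinating Schwann and -1.61 to 1.29 for endothelial nuclei. For the neuron class it was 0.85 without WT1, so its sign rested on that library.

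**Figure D2:**
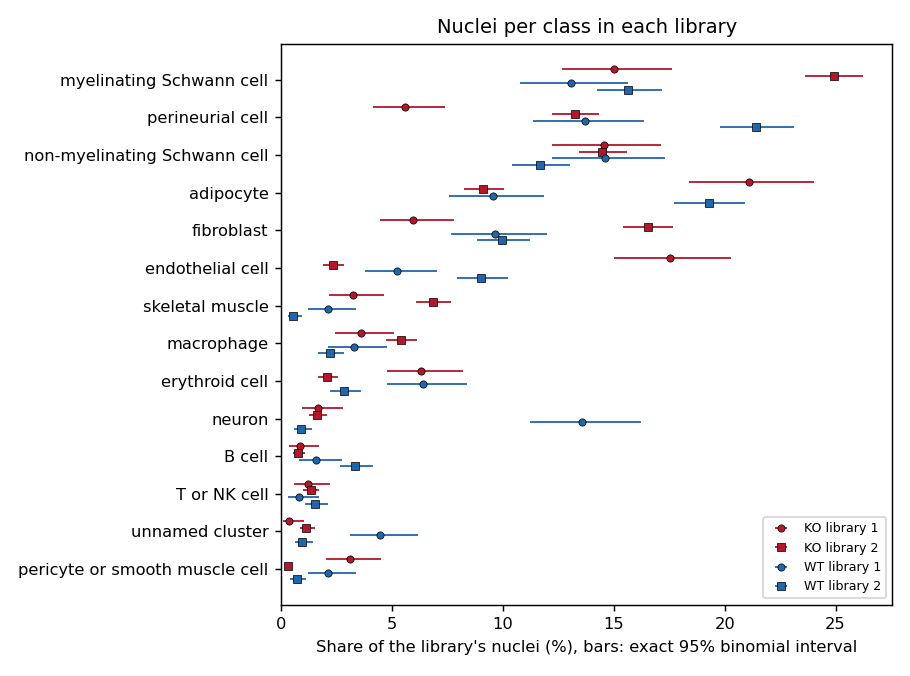
Share of each library's nuclei in each class (horizontal axis, percent) with exact 95% binomial intervals, which cover counting error only; red KO, blue WT. The neuron class was 13.6% of WT1 and between 0.906% and 1.67% of the other libraries, and 3 of its 14 KO1 nuclei had 2 or more neuron markers.

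The second comparison asked which genes differed between the genotypes when the counts of all nuclei were summed in each library. Among the genes of smallest p on the higher side were the atrophy-linked ubiquitin ligases Trim63 and Fbxo32. They stood at 296 and 891 against 24.6 and 5.81 CPM and at 292 and 851 against 56.8 and 30.7 CPM. Myf6, a muscle transcription factor, had 6.85 and 6.24 against 0.506 and 0.166 CPM, and Clip1, a microtubule plus-end protein, had 332 and 437 against 114 and 112 CPM (log2 fold change 1.76, SE 0.30). Arrdc2, an arrestin-domain gene, had 47.4 and 54.6 against 16.4 and 15.4 CPM. On the lower side, Pi16, a marker of adventitial fibroblasts, had 18.0 and 27.5 against 67.3 and 80.3 CPM (log2 fold change -1.71, SE 0.37), Smoc1 40.3 and 35.0 against 81.0 and 73.0, and Btla, a lymphocyte receptor, 13.4 and 7.28 against 29.5 and 31.7. P2rx2, an ATP-gated channel of sensory neurons, had 2 UMIs in KO and 33 in WT, a ratio of 18.1 in favour of WT (95% counting interval 4.63 to 156), and Fam83a 0.571 and 0.52 against 4.22 and 3.15 CPM. None of the 15880 genes tested passed with edgeR, where 177 had an unadjusted p under 0.05. DESeq2 called 3, which were Trim63 (adjusted p = 9.9e-08), Fbxo32 (adjusted p = 3.2e-05) and Clip1 (adjusted p = 0.0246), all higher in KO and named here after their values were seen. Without 1 library edgeR called between 0 and 18 genes, and sums over all nuclei move with the mix of cell types, muscle included.

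Of the 24 gene lists fixed in advance that could be tested over all nuclei, 12 passed camera with its preset correlation. Myelin genes, the structural proteins and lipid enzymes of the sheath, were higher, with 17 of 19 members above 0 and a median log2 fold change of 0.34 (0.30 and 0.55 within library numbers; adjusted p = 2.2e-04, and adjusted p = 0.391 with an estimated correlation). The genes of nodose neuron identity were lower, with 7 of 7 members, such as Phox2b and Isl1, below 0 and a median of -2.11 (within numbers -1.23 and -0.14; adjusted p = 2.7e-05, and adjusted p = 0.391 with an estimated correlation). Neuron-class nuclei were 13.6% of WT1 against 0.906% to 1.67% of the other libraries. Outside KO1 and the forebrain nuclei of KO2 they carried sympathetic genes at 3588 to 5154 CPM and vagal sensory genes at 91.2 to 483 CPM. FoxO target genes (median 0.22, mean 0.76, 18 of 22 above 0) and mitochondrially encoded genes (median 0.67, 12 of 13 above 0) were higher, with adjusted p = 0.391 and 0.544 with an estimated correlation. Genes of cholesterol and fatty acid synthesis (median -0.46), vagal sensory receptors (-0.52), transmitters and neuropeptides (-1.72) and antigen presentation and the interferon response (-0.40) were lower, with adjusted p from 0.529 to 0.544 with an estimated correlation. Nuclear-encoded respiratory chain genes (0.45), immediate early genes (0.36), cytosolic ribosomal proteins (0.26) and heat shock genes (0.60) were higher, with adjusted p from 0.544 to 0.777 with an estimated correlation. No list member passed on its own; adjusted over the list alone, 2 FoxO target genes passed and no member of the other lists. Only the myelin and nodose lists kept their call without each library. FoxO targets lost it without KO1 (adjusted p = 0.193) or WT1 (0.203), cholesterol synthesis without WT1 (0.581), vagal receptors without KO1 (0.447) or WT1 (0.0551), the interferon list without KO2 (0.334) or WT1 (0.872) and mitochondrial genes without WT1 (0.203). Transmitters reversed without KO1 (0.321) and lost the call without WT1 (0.581), and respiratory chain genes reversed without KO1 (0.00252) and lost it without WT2 (0.548). Immediate early genes lost it without KO1 (0.712) and reversed without WT1 (0.79), heat shock genes reversed without KO1 (0.797) and lost it without WT2 (0.516), and ribosomal proteins reversed without KO1 (0.00914) and WT2 (0.0159).

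The third comparison was made within skeletal muscle nuclei, which neck muscle beside the nerve can contribute, and 34 of 2994 genes passed edgeR (7 higher and 27 lower in KO; 393 had an unadjusted p under 0.05). The ubiquitin ligases of muscle atrophy rose, Trim63 from 715 and 1130 CPM in WT to 7669 and 9049 in KO (log2 fold change 3.13, SE 0.58, edgeR adjusted p = 0.031) and Fbxo32 from 856 and 1329 to 6830 and 8411 (2.75, SE 0.57, edgeR adjusted p = 0.0427). Arrdc3, an arrestin-domain gene, rose from 36.6 and 0 to 1104 and 424 CPM, and Spns2, the sphingosine-1-phosphate exporter, had 285 UMIs in KO and 1 in WT, a ratio of 57.2 (95% counting interval 10.2 to 2266). Lpin2, a phosphatidate phosphatase, had 346 UMIs in KO and 0 in WT, at least 23.1-fold higher against a floor of 3 UMIs over the group (edgeR adjusted p = 0.0427). Among the genes that fell, Myh1, the myosin heavy chain of type IIx fibres, had 48.0 and 13.3 CPM in KO against 2084 and 2127 in WT (log2 fold change -6.51, SE 0.85, edgeR adjusted p = 0.00416; within numbers -5.38 and -7.12). Myom3, an M-band protein, had 3 UMIs in KO and 60 in WT, a ratio of 99.7 in favour of WT (95% counting interval 32.5 to 497), and Lmcd1, a regulator of GATA6, 3 and 330, a ratio of 548 (186 to 2673). Ppara, a nuclear receptor that drives fatty acid oxidation, fell from 465 and 598 to 88.0 and 33.2 CPM (log2 fold change -3.44, SE 0.62, edgeR adjusted p = 0.0299).

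Other genes that passed in muscle were read after their values were seen. Pfkfb3, which makes an activator of glycolysis, rose from 26.1 and 66.5 to 616 and 347 CPM, and Slc39a14, a zinc importer, also rose (log2 fold change 3.86, SE 0.82, edgeR adjusted p = 0.0428). Esrrg, a nuclear receptor of oxidative fibres, fell from 1462 and 731 to 56.0 and 91.8 CPM, Jph2, which couples the surface membrane to the sarcoplasmic reticulum, fell by 2.63 on the log2 scale, and Agbl1, Nrp1, Zfp385b, Prkg1 and Ablim1 fell as well. Without KO1 none of these kept its call but Zfp385b (edgeR adjusted p from 0.058 for Nrp1 to 0.689 for Prkg1), and Zfp385b lost it without KO2 (0.134) and WT1 (0.0946). Jph2 (0.523) and Prkg1 (0.148) also lost it without KO2, and Pfkfb3 (0.186), Slc39a14 (0.327) and Ablim1 (0.12) without WT1. Type IIb myosin Myh4, not among the called genes, was at 680, 448, 903 and 266 CPM, type IIa myosin Myh2 at 0, 13.3, 3833 and 266, and type I myosin Myh7 at 0 in all 4 libraries.

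FoxO target genes, which insulin signalling restrains, were higher in muscle as a group: 2 of 12 tested members rose (Trim63 and Fbxo32), 10 did not pass, 9 were above 0 and the median was 0.92 (camera adjusted p = 0.00582; adjusted p = 0.415 with an estimated correlation; 2 adjusted over the list alone). Genes of lipid storage and fatty acid oxidation were lower, with Ppara as the 1 member of 10 that fell, 8 below 0 and a median of -1.96 (camera adjusted p = 2.2e-04; adjusted p = 0.415 with an estimated correlation; 7 adjusted over the list alone). Autophagy and lysosome genes were higher, with 10 of 11 above 0, none passing and a median of 0.97 (camera adjusted p = 0.0485; adjusted p = 0.415 with an estimated correlation). Without WT1 all 3 lists missed the threshold (adjusted p = 0.0903, 0.0549 and 0.197), and the autophagy list also without KO1 (0.129). The count of genes was 20 without WT1, 285 without WT2, 35 without KO1 and 28 without KO2, and of the 34 genes 9, 34, 7 and 13 were among them. Trim63, Fbxo32 and Ppara lost their call without KO1 (edgeR adjusted p = 0.251, 0.393 and 0.113) and without KO2 (0.134, 0.273 and 0.284), Arrdc3 without KO1 (0.0919), and Lpin2 and Spns2 without WT1 (0.148 and 0.124), all with unchanged direction. Without WT1 the fold changes of Arrdc3 and Spns2 rest on 0 UMIs in WT2 and have no upper bound. Myh1 kept its call without each library, and Lmcd1 and Myom3 without KO1, KO2 or WT2. Without WT1 neither Lmcd1 nor Myom3 could be tested, nor could Lpin2 without KO2, so their dependence on these libraries was not checked. Counting intervals given for muscle genes pool the libraries of a genotype and leave out the spread between them. The WT sums rested on 191491 and 15044 UMIs from 16 and 13 nuclei, against 125041 and 904626 UMIs in KO.

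**Figure D3:**
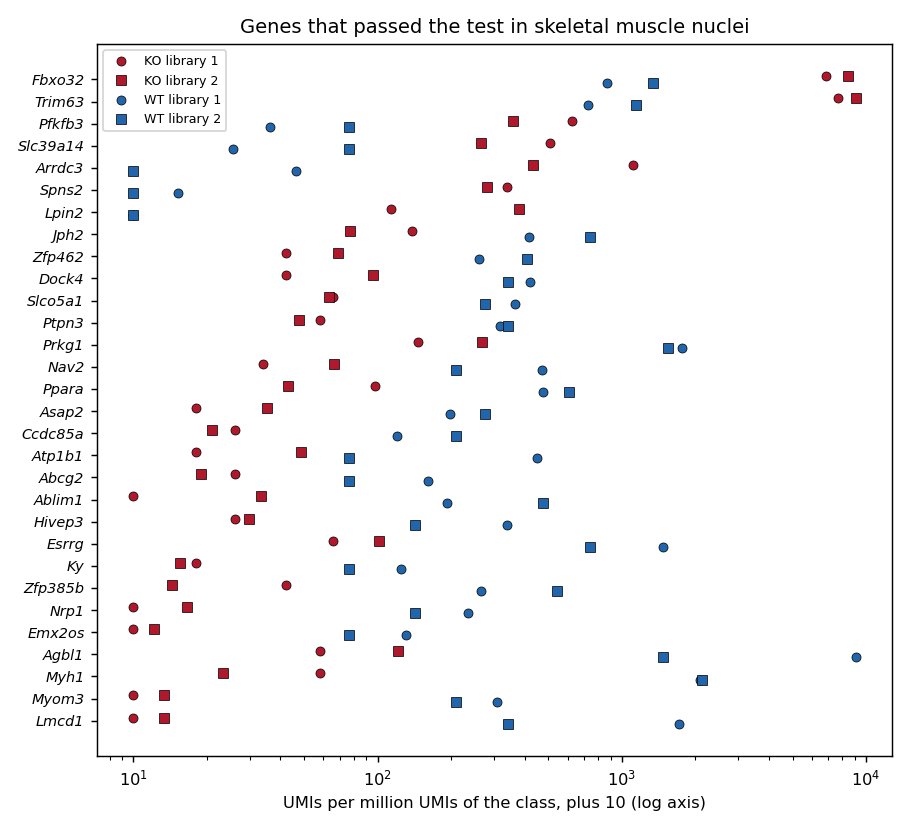
Level of each named gene that passed in skeletal muscle nuclei, in CPM of the class plus 10 on a log axis, 1 point per library (red KO, blue WT). Trim63 and Fbxo32 lay between 6830 and 9049 in KO and between 715 and 1329 in WT.

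Muscle transcripts were also counted in nuclei of other classes. Outside muscle Trim63 was at 23.1 and 44.1 CPM in KO and 1.57 and 3.00 in WT, Fbxo32 at 50.03 and 65.2 against 30.2 and 27.5, and Ttn, the giant sarcomere protein, at 119 and 157 against 96.9 and 7.16. Acta1 stood at 237, 6.66, 105 and 2.33 CPM, Neb at 45.9, 30.1, 34.5 and 4.49 and Myh4 at 182, 11.3, 47.9 and 0.999, each higher in KO by the mean but lower in KO2 than in WT1. These levels stand beside each class below in which Trim63, Ttn or Fbxo32 had a small p.

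In myelinating Schwann nuclei the question was which genes of the myelin-forming cell differed with genotype. None of 7478 genes passed edgeR, though 81 did with the replicate number as a block, a pairing the labels do not state. Without the block 86 had an unadjusted p under 0.05, and DESeq2 called none. The smallest p on the higher side belonged to Trim63 (83 UMIs in KO and 2 in WT, a ratio of 25.9, 95% counting interval 6.95 to 217), the mitochondrial genes mt-Nd2 (608 and 467 against 243 and 272 CPM) and mt-Co1 (log2 fold change 1.14, SE 0.30), the fibrillar collagen Col3a1 (119 and 94.7 against 37.6 and 48.8 CPM) and the protocadherin Pcdh7 (400 and 310 against 153 and 206). On the lower side were Cadm3, an adhesion molecule between axon and Schwann cell (94.9 and 96.8 against 183 and 181 CPM; log2 fold change -0.92, SE 0.24), Pla2g7 (11.9 and 24.9 against 57.5 and 63.0), Samd5 (65.2 and 105 against 212 and 143), the insulin-degrading enzyme Ide (38.5 and 46.3 against 86.2 and 80.3) and Lsamp (71.2 and 64.8 against 108 and 135). Of 18 lists, 3 passed camera, all higher: mitochondrially encoded genes (median 0.99, 12 of 13 above 0, within numbers 1.59 and 0.45; adjusted p = 2.5e-12), cytosolic ribosomal proteins (0.64, 70 of 72 above 0; adjusted p = 2.0e-07) and nuclear-encoded respiratory chain genes (0.31, 21 of 24 above 0; adjusted p = 0.0325). Each had an adjusted p = 0.833 with an estimated correlation, and 10 mitochondrial genes passed adjusted over the list alone. Without KO1 or WT2 the ribosomal list (adjusted p = 0.137 and 0.475) and the respiratory chain list (0.264 and 0.681) changed sign, while the mitochondrial list kept its call without each library.

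Non-myelinating Schwann nuclei, which ensheath small axons, were examined in the same way. None of 7049 genes passed edgeR (smallest adjusted p = 0.372), though 7 did with the replicate number as a block, a pairing the labels do not state. Without the block 120 had an unadjusted p under 0.05, and DESeq2 called none. Trim63 had 65 UMIs in KO and 0 in WT, at least 18.3-fold higher against a floor of 3 UMIs over the group, and Gria2, an AMPA receptor subunit, had 74 and 2 UMIs, a ratio of 31.3 (95% counting interval 8.36 to 263). Pde10a had 156 and 237 against 75.1 and 40.8 CPM, Ntm 150 and 104 against 34.2 and 52.1, and mt-Nd2 589 and 437 against 260 and 281. Lower in KO, without passing, were Trim30a, an interferon-induced gene (0 and 4.44 against 61.5 and 24.9 CPM), Stat1, the transcription factor of the interferon response (38.2 and 54.4 against 109 and 99.6; log2 fold change -1.14, SE 0.35), Enox1 (156 and 148 against 244 and 294), Prkg1 (log2 fold change -1.01, SE 0.29) and Mctp1 (76.4 and 88.8 against 131 and 197). The list of antigen presentation and interferon response genes was lower by the test, with 11 of 14 below 0, none passing and a median of -0.90 (within numbers -0.72 and -0.73; camera adjusted p = 1.2e-05; adjusted p = 0.786 with an estimated correlation). Members below 0 included Stat1, Stat2, Gbp2, Ifit3 and Tap1, and the 3 members above 0 were the antigen presentation genes B2m (log2 fold change 0.039), H2-D1 (0.55) and H2-K1 (0.32). These genes were picked out after their values were seen. The call was lost without KO2 (adjusted p = 0.363) and without WT1 (0.16). Mitochondrially encoded genes (median 0.91, 13 of 13 above 0, adjusted p = 4.9e-10, 6 adjusted over the list alone) and extracellular matrix genes (0.28, 16 of 18 above 0, adjusted p = 8.0e-04) were higher and kept their call without each library. Their adjusted p was 0.825 and 0.786 with an estimated correlation. Myelin genes (0.50, 12 of 14 above 0, adjusted p = 0.0144) and ribosomal proteins (0.33, 65 of 72 above 0, adjusted p = 0.00475) were also higher, each with adjusted p = 0.825 with an estimated correlation. Mpz in these nuclei stood at 3555, 808, 1487 and 654 CPM, against 33553, 12483, 25946 and 14464 in myelinating Schwann nuclei, so free Schwann RNA was not told apart from the nuclei's own. Without KO1 the myelin list (adjusted p = 0.878) and the ribosomal list (1.2e-06) were reversed, and without WT2 the first lost its call (0.362) and the second was reversed (0.00534).

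Perineurial nuclei gave no gene past edgeR's threshold among 9643 (smallest adjusted p = 0.407), though 16 passed with the replicate number as a block. Without the block 105 had an unadjusted p under 0.05, and DESeq2 called none. Trim63 had 53 UMIs in KO and 1 in WT (ratio 72.6, 95% counting interval 12.5 to 2919) and Ttn 48.9 and 69.3 against 20.9 and 8.94 CPM. The synaptic scaffold gene Frmpd4 had 120 and 84.9 against 26.8 and 37.4 CPM (log2 fold change 1.58, SE 0.35), the imprinted RNA Meg3 190 and 194 against 83.8 and 108, and Dpf3 38.0 and 17.9 against 5.82 and 5.69. Lower values were found for Angpt1, a ligand of the vessel receptor Tie2 (27.2 and 26.1 against 91.9 and 51.2 CPM), Homer2 (152 and 180 against 264 and 257), Lrrtm3 (log2 fold change -2.79, SE 0.87), Tmem70 (0 and 5.22 against 17.4 and 18.7 CPM) and Gpr137c (-2.46, SE 0.87). Mitochondrially encoded genes were the 1 list of 19 that passed (median 0.90, 13 of 13 above 0, within numbers 1.37 and 0.59; adjusted p = 5.9e-05, and adjusted p = 0.923 with an estimated correlation). It lost its call without KO2 (adjusted p = 0.565) and without WT1 (0.725).

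The neuron class held different cells in different libraries. The 14 KO1 nuclei carried few neuron markers, summed at 1022 CPM against 20452, 16723 and 22238 in KO2, WT1 and WT2, and 13033 CPM of Mpz. In KO2, 19 of 67 nuclei carried forebrain neuron genes at a summed 6614 CPM and peripheral neuron genes, such as Prph and Phox2b, at 4.11 CPM, and held 487152 UMIs with a median of 16820. The remaining neuron nuclei of KO2, WT1 and WT2 carried sympathetic genes at a summed 4532, 3588 and 5154 CPM and vagal sensory genes at 91.2, 125 and 483 CPM. Over these 174 nuclei, 79.9% had a UMI of Dbh, which makes noradrenaline, 66.7% of Th, which makes its precursor, and 85.6% of Slc6a2, the noradrenaline transporter. Myelinating Schwann nuclei, which should lack these genes, had shares of 3.96%, 0.989% and 4.02% at a median of 1161 UMIs against 3385.5. P2rx3 and Slc17a6 of vagal sensory neurons had UMIs in 1.72% and 2.87% of the neuron nuclei against 0.330% and 0% of the Schwann nuclei, and Calca had none.

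**Figure D4:**
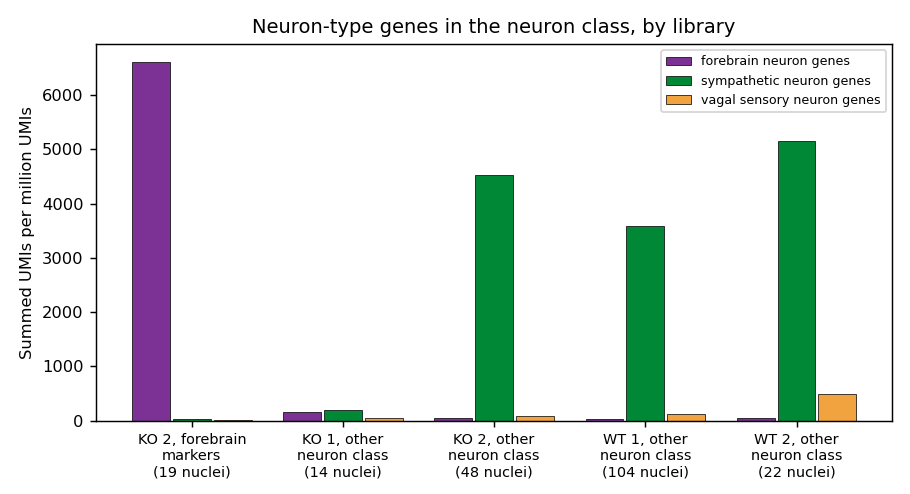
Summed level of forebrain, sympathetic and vagal sensory neuron genes (vertical axis, CPM) in groups of neuron-class nuclei by library. Forebrain genes reached 6614 in 19 KO2 nuclei, while sympathetic genes reached 3588 to 5154 in the other KO2, WT1 and WT2 nuclei.

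None of 7961 genes passed edgeR between genotypes in the neuron class. Of these 144 had an unadjusted p under 0.05, and DESeq2 called none. Among the smallest p were Egr3, an activity-induced transcription factor (88 UMIs in KO and 2 in WT, ratio 62.2, 95% counting interval 16.7 to 522), Epha6 (102 and 179 against 6.60 and 9.11 CPM), Sphkap (51.1 and 163 against 4.95 and 9.11), AI593442 (45 UMIs and 1, ratio 63.7, 10.9 to 2569) and Fam81a (51.1 and 56.8 against 4.95 and 0 CPM). In KO1 51.1 CPM is 1 UMI and 102 CPM is 2, and in WT2 9.11 CPM is 1. On the lower side, Prkcd had 1 UMI in KO and 45 in WT, the interferon-induced GTPase Iigp1 2 and 61, the viral RNA sensor Ddx58 3 and 70 and Adamtsl3 3 and 41, with ratios of 31.8 (95% counting interval 5.43 to 1284), 21.6 (5.72 to 182), 16.5 (5.42 to 81.9) and 9.66 (3.08 to 48.8) in favour of WT. Arhgap6 had 0 and 6.56 against 80.8 and 127 CPM. Of 21 lists, 7 passed camera. Vagal sensory receptors (5 of 5 below 0, median -1.60, such as Htr3a and Piezo2; adjusted p = 0.00502), transmitters and neuropeptides (7 of 7 below 0, -1.61; adjusted p = 0.00923) and cholesterol and fatty acid synthesis (25 of 26 below 0, -0.94; adjusted p = 5.3e-05) were lower. Myelin genes (1.58, within numbers 3.46 and -0.82), ribosomal proteins (0.37, within 1.85 and -0.9998), mitochondrially encoded genes (0.86, within 2.38 and -0.19) and extracellular matrix genes were higher by the test. For the matrix list the median was -0.04 and the mean 0.20, so median and test differed in sign. Adjusted p values of the 7 lists were from 0.611 to 0.627 with an estimated correlation. Only the receptor list kept its call in every fit that left out a library and could test it. Without KO1 the myelin (adjusted p = 3.1e-05), ribosomal (4.3e-14) and matrix (0.125) lists reversed and the transmitter (0.84) and mitochondrial (0.0604) lists lost their call. The matrix and transmitter lists lost it without WT2 (0.125 and 0.225) and the cholesterol list without KO2 (0.209). With the 19 forebrain nuclei left out, a setting chosen after they were seen, the cholesterol and transmitter lists did not pass (adjusted p = 0.0674 and 0.0922).

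Adipocyte nuclei, from fat tissue along the nerve, were compared in the same way. None of 10048 genes passed edgeR, and 278 had an unadjusted p under 0.05. DESeq2 called 1, Trabd2b (2.50 and 5.30 against 97.9 and 20.7 CPM, DESeq2 adjusted p = 0.0197), named here after its value was seen. Trp53inp1, a p53-induced gene, had 288 and 314 against 97.9 and 130 CPM, the collagen hydroxylase P4ha1 156 and 125 against 59.1 and 60.4, and haem oxygenase Hmox1 33.1 and 68.8 against 10.97 and 13.03. Tenm2 had 48.1 and 59.8 against 118 and 182 CPM, Sh2d4a 24.4 and 19.7 against 57.4 and 54.5, and Slc25a21 1.87 and 3.78 against 32.9 and 14.2. Of 19 lists, 9 passed camera. Genes of antigen presentation and the interferon response (8 of 9 below 0, median -1.01, within numbers -1.02 and -0.25; adjusted p = 1.4e-04), insulin and IGF signalling (15 of 18 below 0, -0.24, such as Irs1), cholesterol and fatty acid synthesis (-0.24), voltage-gated channels (-0.45) and extracellular matrix (-0.24) were lower. Beside the first list, the 1 immune-cell marker outside it that could be tested in these nuclei had a log2 fold change of -1.16. B cell nuclei were 0.802% of KO and 2.45% of WT libraries. Macrophage nuclei, at 4.48% and 2.72%, and T or NK cell nuclei, at 1.26% and 1.15%, went the other way by the mean. Immune classes thus did not all differ in the same direction. Heat shock genes (7 of 7 above 0, median 0.92, within 0.92 and 0.43; adjusted p = 6.0e-05), ribosomal proteins (0.35), respiratory chain genes (0.38) and immediate early genes (0.08, within 1.40 and -0.77) were higher. Adjusted p was 0.555 with an estimated correlation for the interferon, insulin, channel and heat shock lists and 0.723 for the other 5. Heat shock genes kept their call without each library, while the interferon list missed the threshold without WT1 (adjusted p = 0.0542). Without KO1 the insulin (0.587), cholesterol (0.648), channel (0.861), ribosomal (0.83) and immediate early (0.319) lists lost their call and the matrix (0.464) and respiratory chain (0.639) lists reversed. Without WT2 the insulin (0.278), channel (0.218), matrix (0.751) and respiratory chain (0.924) lists lost it and the ribosomal list reversed (0.394). The cholesterol and channel lists also lost it without WT1 (0.67 and 0.158), and the immediate early list lost it without KO2 (0.178) and reversed without WT1 (0.00354).

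In endothelial nuclei none of 6021 genes passed edgeR, 158 had an unadjusted p under 0.05 and DESeq2 called none. Among the smallest p, S100a13 had 142 and 106 against 27.6 and 22.2 CPM, the myelin protein gene Mpz 444 and 708 against 134 and 155, and Adgrg6, an adhesion receptor, 60.7 and 101 against 296 and 234. The genes mt-Co1, Carmil1 and Parp8 had log2 fold changes of 1.22, -2.14 and -1.35. Of 19 lists, 7 were higher by camera. Immediate early genes, transcribed soon after a stimulus and here led by Klf2 and Klf4, had a median of 1.32 (within numbers 1.57 and 1.10; adjusted p = 4.2e-08, adjusted p = 0.2505 with an estimated correlation, 4 adjusted over the list alone). Mitochondrially encoded genes had a median of 1.05 (1.19 and 1.12; adjusted p = 1.0e-11, adjusted p = 0.2505 with an estimated correlation, 9 adjusted over the list alone), and were the 1 list in any class that passed fry (adjusted p = 0.0379), which asks whether a list's genes move one way and compares them with no others. Myelin genes had a median of 1.09 (3 adjusted over the list alone), respiratory chain genes 0.88, ribosomal proteins 0.46 (within -0.40 and 2.21), FoxO targets 0.42 and extracellular matrix genes 0.40 (1 adjusted over the list alone), with adjusted p from 0.647 to 0.802 with an estimated correlation. Myelin RNA was found in every class, and its free part was not told apart from the nuclei's own: Mpz stood at 106, 379, 221 and 132 CPM in fibroblast, 204, 423, 810 and 513 in macrophage and 86.8, 243, 127 and 89.4 in adipocyte nuclei. The immediate early, mitochondrial and myelin lists kept their call without each library. FoxO targets lost theirs without KO1, KO2 or WT1 (adjusted p = 0.0625, 0.0561 and 0.358) and the matrix list without KO2 (0.234) or WT1 (0.412). Respiratory chain genes lost theirs without KO1 (0.834) and reversed without WT2 (0.857), and ribosomal proteins reversed without WT2 (3.5e-05).

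In fibroblasts none of 7489 genes passed edgeR and 179 had an unadjusted p under 0.05. DESeq2 called 2, both lower in KO and named after their values were seen: Pi16, a marker of adventitial fibroblasts (258 and 158 against 707 and 774 CPM, DESeq2 adjusted p = 0.0207), and Gpr39, a zinc-sensing receptor (11.2 and 20.4 against 195 and 87.6 CPM, DESeq2 adjusted p = 0.0353). Alcam had 28.0 and 51.3 against 177 and 173 CPM and Lgi1 5.60 and 4.92 against 47.8 and 42.9. Hmcn2 had 258 and 203 against 118 and 76.9, Ttn 106 and 191 against 39.9 and 16.1, and Trim63 65 UMIs in KO and 0 in WT, at least 14.4-fold higher against the floor. Ribosomal proteins were higher (median 0.46, within 1.17 and 0.11; camera adjusted p = 3.2e-10; adjusted p = 0.96 with an estimated correlation) and reversed without KO1 (0.892). No other of the 19 lists passed.

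Macrophage, erythroid and pericyte or smooth muscle nuclei gave no gene past edgeR's threshold among 2627, 2719 and 1179, with 94, 31 and 30 at an unadjusted p under 0.05. DESeq2 called none in any of them, and with the replicate number as a block 1 gene passed in erythroid nuclei. In macrophages Adam33 had 230 and 149 against 40.0 and 55.9 CPM, Ssbp2 310 and 339 against 79.99 and 159, and Cobll1 8.85 and 51.1 against 240 and 233. Arhgap6, Nkain2 and Pcdh9 had log2 fold changes of 1.85, -2.21 and -2.01 there, and none of 9 lists passed. In pericyte or smooth muscle nuclei Nampt, which makes NAD precursors, had 405 and 300 against 101 and 78.2 CPM, Cdh19 36.8 and 37.5 against 457 and 274, and Gpc6 674 and 675 against 2498 and 2581. Mitochondrially encoded genes were the 1 of 7 lists that passed there (median 0.82; adjusted p = 5.0e-04, and adjusted p = 0.927 with an estimated correlation), and not without KO1 (0.715) or WT2 (0.0746). In the erythroid class, whose haemoglobin markers summed to 816 and 723 CPM in KO1 and WT1 but to 767188 and 802061 in KO2 and WT2, Fbxo32 and Trim63 had log2 fold changes of 2.55 and 2.60, and Adgrb3 had 3 UMIs in KO and 52 in WT, a ratio of 15.1 in favour of WT (95% counting interval 4.89 to 75.6). Myelin genes passed there (median 0.95, 1 of 15 lists; adjusted p = 0.00544, and adjusted p = 0.883 with an estimated correlation), and not without KO1 (0.945) or WT2 (0.384). Mpz there stood at 13483, 296, 4003 and 56.3 CPM, and 9.43% and 20.4% of the KO1 and WT1 nuclei of the class had 2 or more of its own markers, against 100% in KO2 and WT2.

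Across the 11 classes, mitochondrially encoded genes were higher in 6 (medians from 0.82 to 1.05) and ribosomal proteins in 6 (0.33 to 0.64). Mitochondrial transcripts took a larger share of UMIs in both KO libraries (1.82% and 0.769%) than in both WT libraries (0.453% and 0.652%). A library-wide difference in mitochondrial RNA carried over with the nuclei was therefore not told apart from a change within each class. With an estimated correlation neither the mitochondrial nor the ribosomal list passed in any class (smallest adjusted p = 0.2505 and 0.627). The ribosomal list changed sign without KO1 or without WT2 in each of its 6 classes. The PI3K-AKT-mTOR list, the pathway that Pten opposes, was tested in all 11 and passed in none (smallest camera adjusted p = 0.0929). Axon regeneration and nerve injury (smallest adjusted p = 0.0907), circadian clock (0.0907), unfolded protein response (0.0624), repair Schwann cell (0.323) and inflammatory mediator (0.464) genes passed in no class, nor did sex-linked genes over all nuclei (0.0768). Jugular neuron and haemoglobin lists had fewer than 5 tested members in every class and were not tested. With an estimated correlation no list passed anywhere, the smallest adjusted p being 0.2505, but with 4 libraries that form has very little power.

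The last comparison tested whether the KO effect differed between neuron-class nuclei and each other class, with edgeR's two-sided test of the genotype by class term. Such genes numbered 5 against adipocytes, 8 against fibroblasts, 5 against myelinating Schwann, 11 against perineurial and 8 against muscle nuclei. Against endothelial, erythroid, macrophage, non-myelinating Schwann and pericyte nuclei none passed, with 194, 77, 140, 185 and 61 at an unadjusted p under 0.05. DESeq2 was not run for this term. They included, read after their values were seen, genes of forebrain neurons: Grin2b and Grin2a, subunits of the NMDA receptor, Satb2, a transcription factor of cortical neurons, Arpp21 and Camk2n1. Without the 19 forebrain nuclei the counts were 1, 1, 0, 1 and 1, a setting chosen after those nuclei were seen. They were also 0 in all 5 without WT1, 0, 0, 0, 0 and 4 without WT2, 81, 120, 27, 90 and 19 without KO1 and 53, 83, 10, 64 and 5 without KO2.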

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

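The neuron-class differences below were fixed for testing in advance; the tests of forebrain nuclei, of WT2 in muscle, of summed immune markers and of repeated thinning were chosen only after the results were seen. What stood out by rule was a KO effect that differed between groups of nuclei. In edgeR's genotype by class test, 5 genes had a KO effect in neuron-class nuclei unlike that in adipocyte nuclei, 8 unlike fibroblast, 5 unlike myelinating Schwann, 11 unlike perineurial and 8 unlike skeletal muscle nuclei. Without WT1 none passed.

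KO2 held 19 neuron-class nuclei with forebrain genes such as Grin2b (2139 CPM), Nrgn (776 CPM) and Satb2 (443 CPM), and Grin2b and Satb2 are among the genes of those differences. Changed vagal or sympathetic neurons of the KO animals are argued against, since 7 peripheral neuron genes summed in them to 0.246% of their level in the other KO2 neuron-class nuclei. Nuclei of another, female mouse fit: Xist took 99.3% of the Xist and Y-linked UMIs in these nuclei (95% interval 97.5 to 99.9%), against 0.61% in all other nuclei of KO2, but 12.1% (7.09 to 18.9%) in its 48 other neuron-class nuclei, from 16 Xist UMIs in 1 nucleus, and 0.313% in other classes, from 16 in 14 nuclei. Without these 19 nuclei the differences numbered 1, 1, 0, 1 and 1. How such nuclei came into the library, and whether these few others share their source, stays open.

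KO and WT skeletal muscle nuclei differed in 34 genes, with Trim63 and Fbxo32 higher and Myh1 lower in KO. The few WT2 nuclei as a cause stay open: without WT2 the signed median log2 fold of these genes was 4.14 against 3.96 with it and 285 genes were called, but the first uses genes called with WT2 in the fit, and fits with a lone library also called 553 genes in neuron and 270 in endothelial nuclei, where none passed with all 4. Different fibre types in the muscle caught with the nerve stay open too, since in nuclei with Myh4 and no Myh1 or Myh2 the signed median was 1.84 against 2.96 in all muscle nuclei, with only 3 such WT nuclei. Feeding state and hour of collection, which also move Trim63 and Fbxo32, are not given and were not tested. A genotype effect in muscle therefore may be real or may come from which muscle was caught and when.

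The list of antigen presentation and interferon response genes was lower in KO non-myelinating Schwann nuclei, with a median of -0.90 (camera adjusted p = 1.2e-05; adjusted p = 0.786 with an estimated correlation), though B2m, H2-D1 and H2-K1 lay above 0. More immune-cell RNA in the WT libraries was left open by the first test, where only 1 marker could be fitted (-0.31), and argued against by the second, where 23 summed markers had a log2 ratio of 0.14. Depth fit by the bound set for the first test, where 1 thinning left 8 members with a median of -0.32, against -0.68 for the same 8 at full depth, and was argued against by the second, where the same 14 members over 20 thinnings had a median of -0.87 (SD 0.13) against -0.78 at full depth. The depth tests differ, so an effect of uneven depth as such stays open. Greater depth of the WT libraries, the form the tests were set for, is argued against by the UMIs of these nuclei. These were 314204 and 901357 in KO against 585606 and 441711 in WT, so both WT libraries lay between the KO libraries. The list summed to 1197 and 476 CPM in KO against 1276 and 736 in WT, and in KO1 B2m, H2-D1 and H2-K1 alone stood at 442, 309 and 146 CPM. The list's median was -0.72 between KO1 and WT1 and -0.73 between KO2 and WT2, while the call was lost when KO2 or WT1 was left out.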

How the results depend on the processing

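Leaving out the forebrain nuclei and clustering without the called muscle genes were chosen only after results were seen; the other alternatives were fixed before. Each fit without 1 library leaves a genotype with 1 sample, and edgeR then assumes that it varies like the others. For every change below the cause was not tested. Over the alternatives, 1548 values of single genes and lists kept both their direction and their side of the threshold of 0.05. Another 97 newly passed it, 163 lost it and 23 reversed direction. Pten, judged by unadjusted p, gave 177 values that kept both, 1 that newly passed and 5 that reversed. These counts follow direction and threshold and do not measure the size of an effect.

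The count of genes changed was 0 in every class but muscle. DESeq2 gave 3 over all nuclei, 1 in adipocytes and 2 in fibroblasts. With no count filter the count was 38 in adipocytes, 16 in endothelial, 23 in fibroblast, 7 in macrophage, 5 in myelinating Schwann, 15 in neuron, 9 in non-myelinating Schwann and 3 in perineurial nuclei, and with library sizes alone 7 in neuron nuclei. In muscle the 34 became 54 with library sizes alone, 54 with no filter, 83 with the stricter filter and 3 with thinned sums. Of the muscle calls 20.6% were higher in KO, against 38.9% with library sizes alone and 44.6% with the stricter filter, while the median log2 fold change of all tested genes was 0.06, and 0.28 with library sizes alone.

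Without 1 library the count of genes changed ranged from 0 to 18 over all nuclei, 0 to 1 in adipocyte, 0 to 270 in endothelial, 0 to 2 in erythroid, 0 to 158 in fibroblast, 1 to 34 in macrophage, 0 to 5 in myelinating Schwann, 0 to 553 in neuron, 3 to 7 in non-myelinating Schwann, 0 to 16 in pericyte or smooth muscle, 0 to 17 in perineurial and 20 to 285 in skeletal muscle nuclei. Pten's log2 fold change ranged from -0.21 to 0.092 in adipocyte, -0.074 to 0.43 in fibroblast and -0.51 to 0.74 in skeletal muscle nuclei. It was 0.86 in endothelial nuclei with thinned sums and 0.039 in muscle with no filter.

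Lists passing numbered 0 in every class and over all nuclei with an estimated correlation, and 0 with fry except 1 in endothelial nuclei. Without 1 library they ranged from 6 to 15 over all nuclei, 3 to 10 in adipocyte, 0 to 3 in erythroid, 1 to 4 in fibroblast, 0 to 2 in macrophage, 1 to 5 in myelinating Schwann, 6 to 12 in neuron, 5 to 8 in non-myelinating Schwann, 0 to 5 in pericyte or smooth muscle, 0 to 3 in perineurial and 0 to 7 in skeletal muscle nuclei.

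Some lists changed sign without a library, and their adjusted camera p ranged as follows. Over all nuclei it was 2.9e-05 to 0.581 for transmitters and neuropeptides, 2.2e-09 to 0.548 for the nuclear-encoded respiratory chain, 2.5e-04 to 0.79 for immediate early genes, 6.1e-16 to 0.0159 for cytosolic ribosomal proteins and 0.0022 to 0.797 for heat shock genes. In adipocyte nuclei it was 4.9e-06 to 0.751 for extracellular matrix, 1.4e-07 to 0.924 for the nuclear-encoded respiratory chain, 5.4e-09 to 0.319 for immediate early genes and 3.1e-15 to 0.83 for cytosolic ribosomal proteins. In endothelial nuclei it was 3.3e-07 to 0.857 for the nuclear-encoded respiratory chain and 2.1e-55 to 1.3e-04 for cytosolic ribosomal proteins, and in fibroblast nuclei 1.3e-20 to 0.892 for cytosolic ribosomal proteins. In myelinating Schwann nuclei it was 1.9e-06 to 0.681 for the nuclear-encoded respiratory chain and 2.9e-25 to 0.475 for cytosolic ribosomal proteins. In neuron nuclei it was 8.2e-09 to 0.00326 for myelin genes, 1.3e-04 to 0.125 for extracellular matrix and 4.3e-14 to 0.00285 for cytosolic ribosomal proteins. In non-myelinating Schwann nuclei it was 4.6e-07 to 0.878 for myelin genes and 3.4e-17 to 0.00534 for cytosolic ribosomal proteins.

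Genes whose KO effect differed between neuron-class nuclei and another class ranged, without 1 library, from 0 to 81 for adipocyte, 0 to 9 for endothelial, 0 to 120 for fibroblast, 0 to 29 for macrophage, 0 to 27 for myelinating Schwann, 0 to 35 for non-myelinating Schwann, 0 to 9 for pericyte or smooth muscle, 0 to 90 for perineurial and 0 to 19 for skeletal muscle nuclei. RLE size factors gave 19 for fibroblast and 13 for skeletal muscle. In the neuron class without the brain-marker nuclei the counts were 1 for adipocyte, 1 for fibroblast, 0 for myelinating Schwann, 1 for perineurial and 1 for skeletal muscle nuclei.

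The log2 ratio of nuclei ranged, without 1 library, from -0.66 to 0.66 for adipocyte, -1.61 to 1.29 for endothelial, -1.14 to 0.54 for erythroid, -0.72 to 0.75 for fibroblast, -3.05 to 0.85 for neuron, -0.011 to 0.32 for non-myelinating Schwann, -2.20 to 1.2002 for pericyte or smooth muscle cell and -0.27 to 0.68 for T or NK cell nuclei. With at least 500 genes and at most 1% mitochondrial counts it was 0.047 for erythroid, -0.12 for non-myelinating Schwann, -0.084 for pericyte or smooth muscle and -0.19 for T or NK cell nuclei, and with no library correction -0.023 for non-myelinating Schwann nuclei.

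With the replicate number as a term (replicate block), 81 genes changed in myelinating Schwann, 7 in non-myelinating Schwann, 16 in perineurial, 1 in erythroid and 89 in skeletal muscle nuclei, and 40.4% of the latter were higher in KO. Lists passing were 3 in fibroblast and 2 in macrophage nuclei. Genes with a different KO effect in neuron-class nuclei were 0 against adipocyte, fibroblast, myelinating Schwann and perineurial and 1 against skeletal muscle nuclei, and the log2 ratio of nuclei was -0.12 for endothelial and -0.33 for pericyte or smooth muscle. The deviations of libraries with the same number correlated at -0.146 over all nuclei, and from 0.11 in neuron to 0.698 in erythroid nuclei. With only 2 numbers and no pairing stated in the labels, a pairing was not established.

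The stricter nuclei filter gave no test in muscle, erythroid, neuron and pericyte or smooth muscle nuclei, and neither components with no library correction nor resolution 1.2 gave one in neuron nuclei, for want of nuclei or of a named cluster; the first gave none in erythroid nuclei either. Depth limits how many genes can be tested: with sums thinned to the smallest library, 251 of 7961 genes remained in neuron and 213 of 2994 in muscle nuclei. Recovery of simulated 4-fold changes did not follow depth, with 59 of 100 in macrophage and 23 in pericyte or smooth muscle nuclei. It was 13 over all nuclei, 4 in muscle and 0 in neuron and erythroid nuclei. A count of 0 in neuron nuclei therefore says little. The same holds for erythroid nuclei, where the simulation tested only 801 genes against 2719 and the power is not known. Of simulated 2-fold changes edgeR recovered at most 13 of 100 in any class (fibroblast), so a count of 0 in any class does not exclude changes of that size.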

Other observations

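The groups below were read only after their values were seen. Adipocyte nuclei fell into a large cluster of 967 nuclei led by genes of brown fat, Ucp1, Cidea, Ppargc1b and Ppara, and a small one of 130 led by Cyp2e1, Car3 and Cfd. Ucp1, which uncouples respiration to make heat, stood at 1188, 505, 830 and 839 CPM (edgeR two-sided adjusted p = 0.998). Ppargc1a, a coactivator of mitochondrial genes, stood at 2724, 1769, 807 and 1858 CPM (log2 fold change 0.74, SE 0.46, edgeR adjusted p = 0.998), and Dio2, which activates thyroid hormone, at 391, 204, 50.6 and 198 (1.23, SE 0.64, edgeR adjusted p = 0.998).

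Cluster 17, unnamed, held 3, 47, 34 and 23 nuclei led by Adgrb3, Ptprz1, Mapk4 and Edil3. Perineurial nuclei fell into clusters of 713 and 510 nuclei, and macrophages into clusters of 282 and 50. Doublet calls took 3.23% of the KO2 nuclei that passed the filter. Barcode sequences found in 2 or more libraries numbered 6. Hbb-bs outside muscle nuclei stood at 306, 19427, 37.6 and 33061 CPM. The median log2 fold change of the interferon list was 0.52 in myelinating Schwann, -0.12 in perineurial, -0.16 in fibroblast, -0.21 in endothelial and -1.69 in neuron nuclei, none of which passed.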
